A study of Arabidopsis thaliana with 12 samples.

How the data were processed

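Transcript levels were measured on 12 single-colour Agilent arrays hybridised with Cy3-labelled cRNA from whole wild-type (Col-0) Arabidopsis thaliana seedlings, with 3 arrays for each of 4 treatments. Seedlings were raised on medium that held the solvent dimethyl sulfoxide (DMSO), 3-bromoindazole (3BRO), 7-nitroindazole (7NIT) or 3-bromo-7-nitroindazole (3B7N), the chemicals at 2.5 µM. The labels do not state whether the arrays of a treatment came from separate cultures, so the p-values measure the spread between these samples, which may be technical. The series' design text also names a cry1cry2 genotype, which was not analysed here.

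Spot intensity values were deposited as scanner output made with Agilent Feature Extraction 10.7.3.1, per the submitters' processing notes, and the processed signal used here is a linear intensity that is already background-corrected, per the file headers. The deposited fold values and corrected p-values came from a separate table of the authors, which lists probes for 3B7N against DMSO and for 7NIT against DMSO. In the authors' deposited table the p-values are named as corrected, the correction is not given in the sources used here, and the folds are linear ratios of 2 or more without a direction.

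The processed signal was taken to log2 and each array's 75th percentile was subtracted. The file of 3BRO replicate 2 holds signals rounded to 3 significant digits, unlike the others, and was used as it is. Control spots and spots marked by the scanner software as non-uniform or as population outliers were left out, and spots of a probe were averaged on the log2 scale. A probe entered the tests if it was marked well above background on all 3 arrays of at least 1 group, which 35752 of 43603 probes were. Of the passing probes, 32124 carried a locus in the files' annotation. Each gene was represented by its brightest passing probe over the 12 arrays, which gave 23536 genes, of which 6605 had more than 1 passing probe. Symbols came from a RefSeq gene table of the TAIR10.1 assembly, which held 23285 of these loci, and the other 251 kept the name in the files. The file headers name an older array build, so the table served for names alone and no coordinates are given. Probes of near-identical gene copies, such as those of the LHCB1, RBCS, SAUR and GSTU families and of KIN1 and KIN2, can bind transcripts of more than 1 copy, so values of single members are uncertain.

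Groups were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with tables read by the data.table package, version 1.17.8. All 12 arrays entered a single fit with 1 coefficient per treatment, and p-values were adjusted by Benjamini-Hochberg within each of 7 comparisons at a threshold of 0.05. The comparisons were each chemical against DMSO, each pair of chemicals, and an interaction, (3B7N minus 3BRO) minus (7NIT minus DMSO). The interaction asks whether the log2 changes with 3BRO and 7NIT add up to that with 3B7N. Intervals are limma's 95% confidence intervals. Counts are also given for a fold of at least 2. The number of arrays limits the precision. Where a probe was not well above background on any array of a group, the fold is given as a lower bound, written as at least. It holds for the processed signal alone and is not a confidence limit. Values after normexp background correction can lie below it or turn. The bound sets the bright group's mean against the mean of the dim group's values, each raised where needed to the lowest signal among probes well above background on that array.

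Gene groups were 29 lists, 19 by locus and 10 by a rule on the annotation. The lists by locus were light-harvesting antenna, photosystem subunits, Calvin cycle, chlorophyll biosynthesis, flavonoid and anthocyanin, photoreceptors and light signalling, PIF-target and shade genes, auxin response, gibberellin and brassinosteroid, cell wall expansion, root and root hair markers, xenobiotic detoxification, oxidative stress, nitrate assimilation and nitric oxide, circadian clock, defence and jasmonate, abscisic acid and cold, seed storage and reserve use, and heat shock and chaperones. The lists by rule were plastid-encoded genes, mitochondrion-encoded genes, cytosolic ribosomal proteins, cytochromes P450, UDP-glycosyltransferases, class III peroxidases, extensins with proline-rich wall proteins, WRKY factors, ethylene response factors and the SAUR family, whose rule also takes in Aux/IAA genes annotated as auxin-responsive proteins. Each list was tested with limma's camera at a preset correlation of 0.01, adjusted over the 29 lists, and again with an estimated correlation. Member counts are given over all genes and adjusted over the list alone.

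Named genes followed a rule. For each chemical against DMSO they were the 10 genes of highest and the 10 of lowest log2 fold change among those past the threshold whose 3 treated arrays all lay above, or all below, the 3 DMSO arrays. For pairs of chemicals and the interaction, 5 and 5 were taken in the same way. From each list up to 4 members could be named, the 2 highest and 2 lowest past the threshold, or the 2 of smallest p where none passed. CRY1, CRY2, PHOT1, PHYA, PHYB, HY5, COP1, PIF4, CHS and LHCB1.1 were always named, and so were the 5 largest and 5 smallest folds per comparison in the authors' deposited table, of which the text gives the largest and, for 7NIT, FSD1 among the smallest. Treatment groups, comparisons, lists, this rule and the other settings to be tried were fixed before the data were examined.

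Slide and scan day came from the files. Slide 1, scanned on the first day, held the 3 DMSO arrays and 3BRO replicate 1. Slide 2 held 3BRO replicates 2 and 3 and 3B7N replicates 1 and 2, and slide 3 held the 7NIT arrays and 3B7N replicate 3, both scanned on a second day. Slide or scan day can be fitted as a block, but each link between slides rests on 1 array (3BRO replicate 1 and 3B7N replicate 3). The fit was tested on simulated data for 3B7N against DMSO, with 23372 genes of which 50 were changed at each of 4 sizes. It called 12% of the genes changed by 0.5 log2, 52% at 1, 86% at 2 and 98% at 4, with 7 calls among 23172 unchanged genes. With slide as a block it called 0%, 2%, 36% and 74% of them, with 1 call among the 23172. The simulation changed a far smaller share of genes than was called in the data, and it held no slide effect. Its shares of changes called may therefore be too low for the data.

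Alternatives were quantile normalisation, the array median, limma's normexp background correction with an offset of 50, no filter on dim probes, a filter on all 12 arrays, the mean of a gene's probes, a fit of only the groups compared, replicate number, slide or scan day as a block, a trend with robust variance, array weights, leaving out each array, and a fold threshold of 2. For normexp, the median foreground signal stood in for the mean foreground signal that had been planned, beside the median background signal. Fits within a slide and slide as a random block were added after the data were seen, and a group with 1 array on a slide was assumed to vary like the others. Similarity between comparisons that share the DMSO arrays was set beside 100 simulations of unchanged groups. In these, each of the 12 arrays was a residual array drawn with replacement from any group, with a random sign. The simulated comparisons share a simulated DMSO group, and no gene changes in them.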

Results

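Expression was profiled in Arabidopsis seedlings that had germinated and grown on 3-bromo-7-nitroindazole (3B7N), a compound studied here for its effect on hypocotyl elongation in blue light, on 3-bromoindazole (3BRO), which lacks the nitro group, on 7-nitroindazole (7NIT), which lacks the bromo group, or on the solvent DMSO. Seeds were kept 3 days in darkness in the cold and then 4 days in continuous blue light of 10 µmol per square metre and second. Each treatment had 3 arrays, and the chemicals were all at 2.5 µM. The 75th percentile of the processed signal was 1768 to 2205 on the DMSO arrays, 2366 to 2920 on the 3BRO arrays, 2770 to 3472 on the 7NIT arrays and 3318 to 3761 on the 3B7N arrays. Between 77.1% and 84.6% of probes were well above background per array, and no probe used here was saturated (0 spots on each array). Log2 signals correlated across genes with r from 0.979 to 0.993 within treatments and from 0.957 to 0.993 between them, where genes are not independent replicates. On the first principal component the 3B7N arrays lay at 91.1, 53.0 and 53.1, and the other 9 arrays lay between -36.7 and -7.2.

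**Figure D1:**
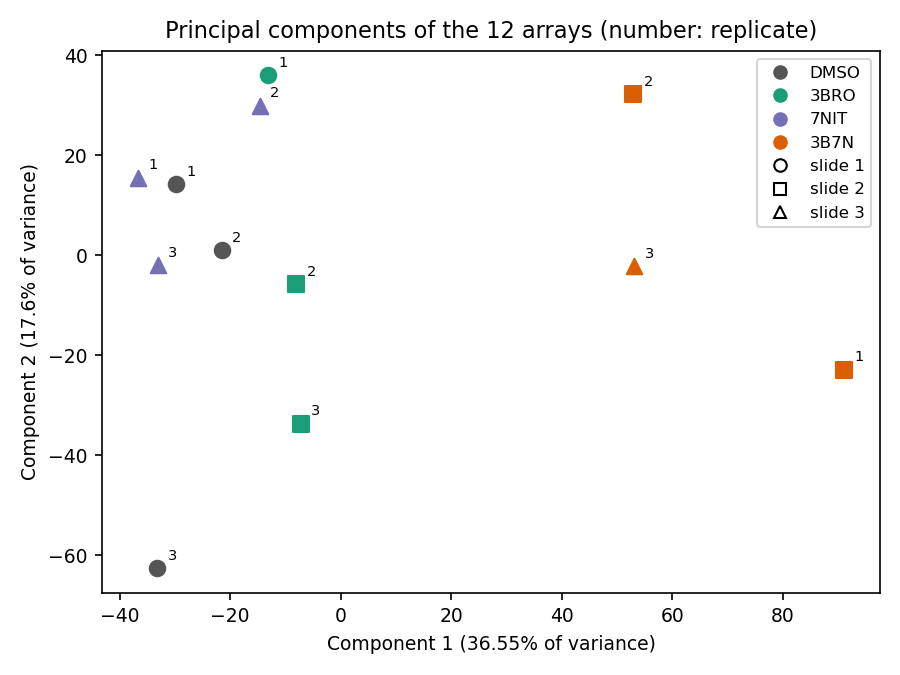
Scores of the 12 arrays on the first 2 principal components of normalised log2 signal, with colour for the treatment, marker shape for the slide and the replicate number beside each point. The 3 arrays of 3B7N lie apart from the other 9 on the first component, at 53.0 or above.

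The comparison of 3B7N with DMSO asks which transcripts change when blue-light-grown seedlings are exposed to the compound. Among the transcripts that rose were those of NATA1, an acetyltransferase of polyamine and ornithine metabolism, ENODL1, an early nodulin-like protein, and DIN11, a dark-inducible dioxygenase. NATA1, ENODL1, CYP71A13, AT3G29060 and SAG13 were not well above background on any DMSO array, so their rank by size is not established. NATA1 rose by 6.48 log2 units (SE 0.55, n = 3 arrays per treatment, limma adjusted p = 0.00013), at least 20.9-fold. ENODL1 rose by 6.43 (SE 0.35, adjusted p = 1.2e-05), at least 44.1-fold, and DIN11, well above background on 2 of 3 DMSO arrays, by 5.93 (SE 0.33, adjusted p = 1.2e-05). PORA, the protochlorophyllide oxidoreductase typical of dark-grown seedlings, rose by 4.27 (SE 0.37, adjusted p = 0.00014). CYP71A13, a cytochrome P450 of camalexin synthesis, rose by 4.49 (SE 0.49, adjusted p = 0.00043), at least 7.31-fold, and the senescence-associated gene SAG13 by 4.09 (SE 0.77, adjusted p = 0.0058), at least 5.42-fold. The same rule named AT4G13790, of the SAUR family, at 4.74, AT3G29060 at 4.22, at least 8.03-fold, AT4G35720 at 4.09 and AT4G17470 at 4.04. With slide as a block the log2 changes were 5.91 for NATA1, 6.14 for ENODL1, 6.75 for DIN11 and 4.37 for PORA, which passed at adjusted p of 0.028, 0.0092, 0.0058 and 0.023. AT4G13790 (3.17, adjusted p = 0.11), CYP71A13 (3.68, adjusted p = 0.076) and SAG13 (2.66, adjusted p = 0.35) did not pass with that block. After normexp background correction NATA1 (1.78, adjusted p = 0.17), ENODL1 (2.31, adjusted p = 0.053), AT4G13790 (2.18), CYP71A13 (0.34), AT3G29060 (0.47) and SAG13 (0.24) lost their call. Apart from AT4G13790, for which no bound is given, these values lie below the folds given as at least.

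At the other end, the cytochrome P450 gene CYP706A6 fell by 5.10 log2 units (SE 0.41, n = 3 arrays per treatment, limma adjusted p = 0.00011) and PIN5, an auxin transporter of the endoplasmic reticulum, fell by 4.97 (SE 0.70, adjusted p = 0.0014). FRO4, a metal reductase of the plasma membrane, fell by 4.91 (SE 0.68, adjusted p = 0.0012). FSD1, the plastid iron superoxide dismutase, fell by 4.23 (SE 0.20, adjusted p = 7.6e-06), and GPX7, a glutathione peroxidase, fell by 3.88 (SE 0.28, adjusted p = 6.1e-05). AT2G30766 was at -5.91 (SE 0.92, adjusted p = 0.0023), AT4G34550 at -4.73, AT3G10185 at -4.54, AT1G47400 at -3.86, at least 5.02-fold lower, and AT2G27395 at -3.76. Under the slide block CYP706A6 was at -4.52 (adjusted p = 0.024), PIN5 at -4.78 (adjusted p = 0.017), FRO4 at -7.38 (adjusted p = 0.011), FSD1 at -3.60 (adjusted p = 0.0034) and GPX7 at -4.34 (adjusted p = 0.0083). AT2G30766 (-3.23, adjusted p = 0.26), AT3G10185 (-3.12, adjusted p = 0.12) and AT1G47400 (-2.99, adjusted p = 0.42) did not pass with it. PIN5 did not pass with scan day as a block (-3.85, adjusted p = 0.14). FRO4 (-2.26, adjusted p = 0.052) and AT1G47400 (-1.21, adjusted p = 0.28) lost their call after normexp background correction.

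**Figure D2:**
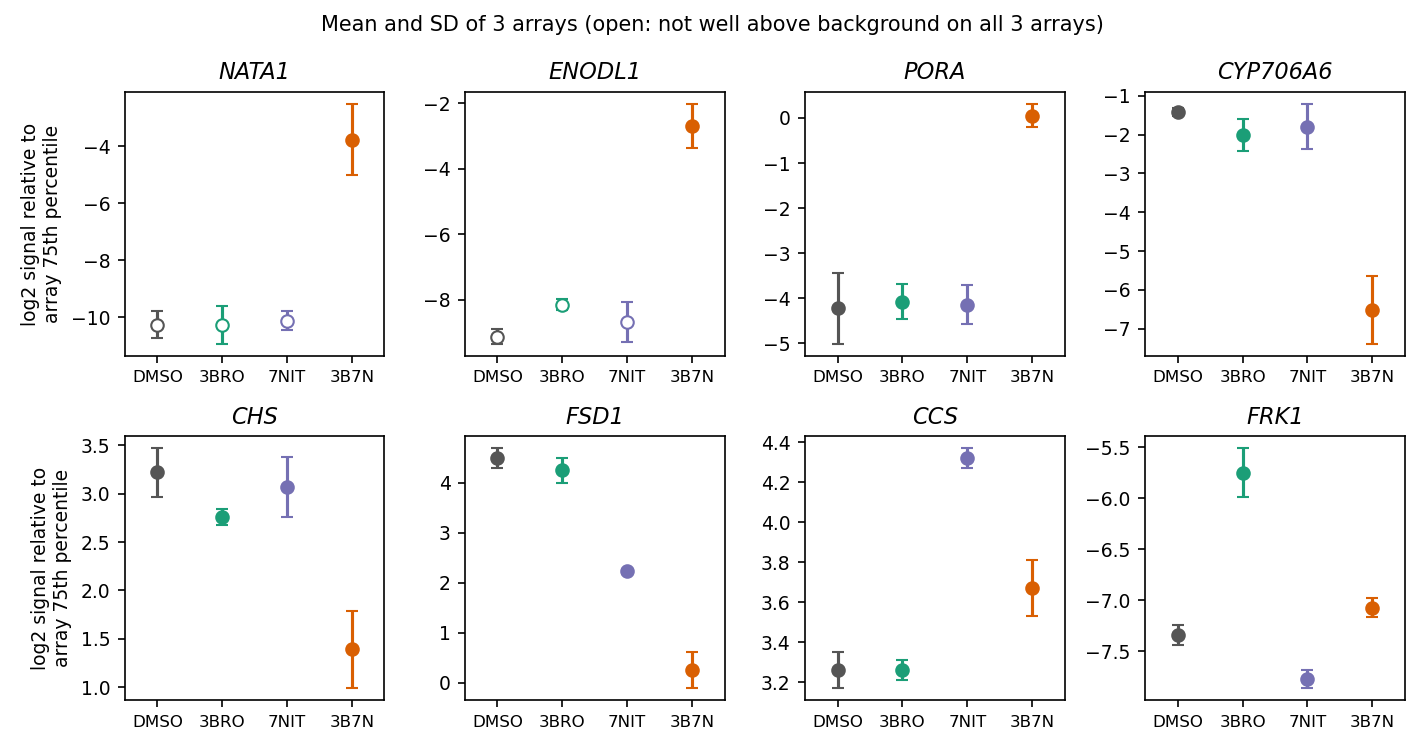
Mean log2 signal relative to the array's 75th percentile, with SD over 3 arrays, for 8 genes in the 4 treatments, where open symbols mark groups not well above background on all 3 arrays. NATA1, ENODL1 and PORA were higher and CYP706A6, CHS and FSD1 lower with 3B7N than with DMSO, while CCS was highest with 7NIT and FRK1 with 3BRO, where the order of FRK1 between 7NIT and 3BRO turned after normexp background correction.

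Lists of the photosynthetic apparatus were lower with 3B7N at camera's preset correlation. In the Calvin cycle, 18 of 18 measured members fell, among them CP12-2, a regulator of the cycle, by 2.14 log2 units (SE 0.26), FBA1, an aldolase, by 1.44 (SE 0.17), and RBCS3B, a Rubisco small subunit, by 0.63 (SE 0.14). Adjusted over the list alone 18 fell as well. Their median was -0.94, and the list was lower by camera (adjusted p = 3.5e-14). It was not called at adjusted p = 0.19 with an estimated correlation. Of 23 photosystem subunits 16 fell, or 20 adjusted over the list alone, such as PSBQ1 by 1.00 (SE 0.14) and PSBY by 0.95 (SE 0.19), with PSAK at -0.56, or 0.01 after quantile normalisation. The photosystem median was -0.63 (camera adjusted p = 3.7e-09), with adjusted p = 0.44 with an estimated correlation. Of 20 light-harvesting antenna genes 9 fell, or 12 adjusted over the list alone, including LHCB4.3 by 2.79 (SE 0.18) and LHCA6 by 1.29 (SE 0.19). LHCB1.1 fell by 0.56 (SE 0.16) and LHCB1.3 by 0.53 (SE 0.14), and after quantile normalisation these 2 stood at 0.04 and 0.08. The antenna median was -0.51 (camera adjusted p = 2.6e-06), with adjusted p = 0.44 with an estimated correlation, and the call ended after quantile normalisation (adjusted p = 0.40). The medians with slide as a block were -0.75 for the Calvin cycle (adjusted p = 1.8e-07), -0.82 for the photosystems (adjusted p = 9.9e-08) and -0.84 for the antenna (adjusted p = 2.5e-07), each at adjusted p = 0.46 with an estimated correlation. With that block 0 of 18 Calvin cycle genes passed by limma, 2 of 23 photosystem genes and 2 of 20 antenna genes. The block also lowered the share of simulated changes of 1 log2 that were called from 52% to 2%. That simulation changed a far smaller share of genes than was called in the data.

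In chlorophyll biosynthesis 12 of 18 genes fell and 1 rose, or 13 and 2 adjusted over the list alone. DVR fell by 1.27 (SE 0.14) and PORC, the oxidoreductase of light-grown tissue, by 1.08 (SE 0.21), while PORA was the member that rose. The median was -0.65 (camera adjusted p = 0.00028), with adjusted p = 0.34 with an estimated correlation, and with slide as a block -0.77 (adjusted p = 0.0086), with 1 higher and 2 lower. The blocked chlorophyll call was lost at adjusted p = 0.49 with an estimated correlation. Among flavonoid and anthocyanin genes 12 of 21 fell, or 15 adjusted over the list alone. FLS1, flavonol synthase, fell by 1.97 (SE 0.36), and CHS, chalcone synthase, which opens the pathway, fell by 1.84 (SE 0.22, adjusted p = 0.00074) and by 2.05 with slide as a block (adjusted p = 0.028). With scan day as a block CHS was at -1.85 and did not pass (adjusted p = 0.051). The flavonoid median was -1.04 (camera adjusted p = 7e-07), with adjusted p = 0.34 with an estimated correlation, and -0.98 with slide as a block (adjusted p = 0.00084), where 1 passed. That blocked call was lost as well, at adjusted p = 0.49 with an estimated correlation. Of 66 plastid-encoded genes 23 fell, or 35 adjusted over the list alone, ATCG00020 by 1.27 and ATCG01240 by 0.48, the last of which stood at 0.01 after quantile normalisation. Their median was -0.66 (camera adjusted p = 4.6e-08), with adjusted p = 0.53 with an estimated correlation, and -0.45 with slide as a block (adjusted p = 0.014), where 0 passed by limma. Of 59 mitochondrion-encoded genes 3 fell, or 2 adjusted over the list alone, with a median of -0.40 (camera adjusted p = 0.011), adjusted p = 0.75 with an estimated correlation and -0.81 with slide as a block (adjusted p = 0.00034). The blocked calls of the plastid-encoded and mitochondrion-encoded lists were each lost at adjusted p = 0.74 with an estimated correlation. The mitochondrial call without a block was lost on leaving out DMSO 3 or 3B7N 2 (adjusted p up to 0.57).

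The detoxification, abscisic acid and cold, and defence lists were higher with 3B7N at camera's preset correlation. In the xenobiotic list 18 of 31 genes rose, or 21 adjusted over the list alone, among them AKR4C9, an aldo-keto reductase, by 2.28 (SE 0.38), and the glutathione transferase GSTU4 by 2.38 (SE 0.43). GSTU3, another, rose at least 2.06-fold but stood at -0.22 log2 units after normexp background correction. The median was 0.83 (camera adjusted p = 2.7e-10), with adjusted p = 0.12 with an estimated correlation, and 0.60 with slide as a block (adjusted p = 0.00034), with 2 higher and 1 lower. The blocked xenobiotic call was lost at adjusted p = 0.46 with an estimated correlation. Of 8 genes of abscisic acid and cold response 6 rose, or 7 adjusted over the list alone, RD29B by 3.24 (SE 0.47) and KIN1 by 2.93 (SE 0.56). Their median was 2.54 (camera adjusted p = 4.2e-06), with adjusted p = 0.19 with an estimated correlation, and 2.17 with slide as a block (adjusted p = 0.00076), where 1 passed. Their blocked call was lost at adjusted p = 0.46 with an estimated correlation. In the defence and jasmonate list 5 of 13 rose over all genes and adjusted over the list alone, including JAZ10, a repressor of jasmonate signalling, by 2.34 (SE 0.55), VSP2 by 1.48 (SE 0.17) and PAD3, of camalexin synthesis, by 0.82 (SE 0.16). The median was 0.95 (camera adjusted p = 9.3e-05), with adjusted p = 0.12 with an estimated correlation, and 1.08 with slide as a block (adjusted p = 0.00076), where 2 passed. This list's blocked call, too, was lost at adjusted p = 0.46 with an estimated correlation.

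The auxin, PIF-target and gibberellin lists were higher at camera's preset correlation without a block and were not called with slide as a block. Of 28 auxin response genes 7 rose, or 9 adjusted over the list alone, such as IAA6 by 4.01 (SE 0.62), IAA20 by 2.56 (SE 0.36) and IAA17 by 0.72 (SE 0.22), which stood at -0.12 with slide as a block. The auxin median was 0.48 (camera adjusted p = 0.00066), with adjusted p = 0.53 with an estimated correlation, and with slide as a block it was -0.39 (adjusted p = 0.27), the other direction. Of 17 PIF-target and shade genes 5 rose, or 7 adjusted over the list alone, among them ST2A, a sulfotransferase of jasmonates, by 2.89 (SE 0.51), IAA19 by 1.99 (SE 0.32), HAT2 by 1.16 (SE 0.27) and PIL1 by 1.13 (SE 0.33). Their median was 0.65 (camera adjusted p = 0.0013), with adjusted p = 0.44 with an estimated correlation, and 0.13 with slide as a block (adjusted p = 0.87). In the gibberellin and brassinosteroid list 2 of 24 rose, GA20OX1, of gibberellin synthesis, by 2.32 (SE 0.35) and GASA4 by 1.03 (SE 0.14), and GA3OX2 fell by 1.09 (SE 0.33), with 2 higher and 2 lower adjusted over the list alone. The median was 0.22 (camera adjusted p = 0.026), with adjusted p = 0.19 with an estimated correlation, and 0.03 with slide as a block (adjusted p = 0.22). The gibberellin call without a block was lost on leaving out DMSO 1 or 3B7N 3 (adjusted p up to 0.08). Of 29 cell wall expansion genes 4 rose, led by XTH17 at 2.66 (SE 0.39), and XTH5 fell by 0.77 (SE 0.19), the same numbers adjusted over the list alone, and the list was not called (median 0.28, camera adjusted p = 0.061).

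Of the photoreceptor transcripts, CRY1 was at -0.16 (95% confidence interval -0.48 to 0.16), CRY2 at 0.22 (-0.08 to 0.52), PHOT1 at 0.32 (0.01 to 0.64) and PHYB at -0.01 (-0.35 to 0.33), and none of these 4 passed. PHYA, the phytochrome of dark-grown tissue, rose by 1.01 (SE 0.21, adjusted p = 0.0091) but stood at 0.48 with slide as a block (adjusted p = 0.49). HY5, a transcription factor of light responses, was at -0.74 (-1.24 to -0.24, adjusted p = 0.051), COP1 at -0.17 and PIF4 at 1.12 (-0.03 to 2.27, adjusted p = 0.17), and these 3 did not pass. In the photoreceptor and light signalling list 3 of 31 rose, among them PIF3 by 1.58 (SE 0.33), and 2 fell, CRY3 by 1.26 (SE 0.20) and BBX25 by 0.95 (SE 0.26), or 3 and 3 adjusted over the list alone. Its median of -0.08 opposed the upward direction of a test that was not called (camera adjusted p = 0.87).

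In the root and root hair list 6 of 18 fell, or 7 adjusted over the list alone, such as PRP3 by 1.81 and EXPA18 by 1.74, with PYK10 at -0.49, or 0.02 after quantile normalisation. The list was not called (median -0.30, camera adjusted p = 0.078). It was called lower under a slide block (-0.49, adjusted p = 0.0011, 4 genes lower) but not at adjusted p = 0.46 with an estimated correlation. In the oxidative stress list 2 of 17 rose and 2 fell, or 6 and 2 adjusted over the list alone, with CAT2, a catalase, at -1.18 and CAT3, another, at 0.90. Its median of -0.06 opposed the upward direction of the uncalled test (camera adjusted p = 0.70). Of 8 nitrate and nitric oxide genes NIA2 fell by 0.76 and NIR1 by 0.68, enzymes of nitrate assimilation, and the same 2 fell adjusted over the list alone (median -0.19, camera adjusted p = 0.39). Of 17 clock genes 3 fell over all genes and adjusted over the list alone, led by RVE1 at -1.15 and LHY at -0.99 (median -0.15, camera adjusted p = 0.40). PCK1, at 0.49, was the 1 of 13 seed storage and reserve genes that rose (median 0.10, camera adjusted p = 0.34), also adjusted over the list alone. That list was higher under a slide block (0.77, adjusted p = 0.019), with adjusted p = 0.74 with an estimated correlation. None (0) of 8 heat shock genes passed over all genes or adjusted over the list alone (median 0.80, camera adjusted p = 0.078), though the list was higher with slide as a block (1.75, adjusted p = 0.00076). That call was lost at adjusted p = 0.46 with an estimated correlation.

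Among enzyme and regulator families, 16 of 215 cytochromes P450 rose and 40 fell, or 19 and 40 adjusted over the list alone, CYP71B36 by 3.35. The family was not called (median -0.14, camera adjusted p = 0.28), but was lower under a slide block (-0.40, adjusted p = 0.0051, with 17 lower and 1 higher). That call was lost at adjusted p = 0.46 with an estimated correlation. Of 59 UDP-glycosyltransferases 13 rose, UGT76E1 by 2.45, and 8 fell, or 16 and 10 adjusted over the list alone (median 0.09, camera adjusted p = 0.078). They were higher under a slide block (0.26, adjusted p = 0.018), with adjusted p = 0.49 with an estimated correlation. Of 11 class III peroxidases 2 rose, PA2 at 2.24 and PRX52, which stood at -0.20 after normexp background correction, and 2 fell, or 3 and 2 adjusted over the list alone (median 0.33, camera adjusted p = 0.26). Of 23 extensins and proline-rich wall proteins 2 rose and 6 fell, EXT11 among them, or 2 and 9 adjusted over the list alone (median -0.32, camera adjusted p = 0.14). Of 70 WRKY factors 5 rose, WRKY28 by 1.31, and WRKY54 fell by 1.18, or 1 and 0 adjusted over the list alone (median 0.09, camera adjusted p = 0.041), with adjusted p = 0.54 with an estimated correlation. The WRKY call was lost with slide as a block (0.10, adjusted p = 0.79), after quantile normalisation (adjusted p = 0.08) or normexp (adjusted p = 0.10), and on leaving out DMSO 3, 3B7N 2 or 3B7N 3 (adjusted p up to 0.18). In the SAUR family 8 of 76 rose and 10 fell, or 11 and 11 adjusted over the list alone (median 0.18, camera adjusted p = 0.39), and with slide as a block the family was lower (-0.75, adjusted p = 0.018). That call was lost at adjusted p = 0.74 with an estimated correlation. Of the 7 cytosolic ribosomal protein genes that the rule found 1 fell, BBC1 by 0.61, or 2 adjusted over the list alone (median -0.39, camera adjusted p = 0.05, called before rounding), with adjusted p = 0.54 with an estimated correlation. The ribosomal call was lost with slide as a block (adjusted p = 0.23), after quantile normalisation (adjusted p = 0.068) or normexp (adjusted p = 0.086), and on leaving out DMSO 1, DMSO 3, 3BRO 1, 7NIT 3 or any 3B7N array (adjusted p up to 0.12). None (0) of 28 ethylene response factors passed over all genes or adjusted over the list alone (median -0.04, camera adjusted p = 0.98).

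**Figure D3:**
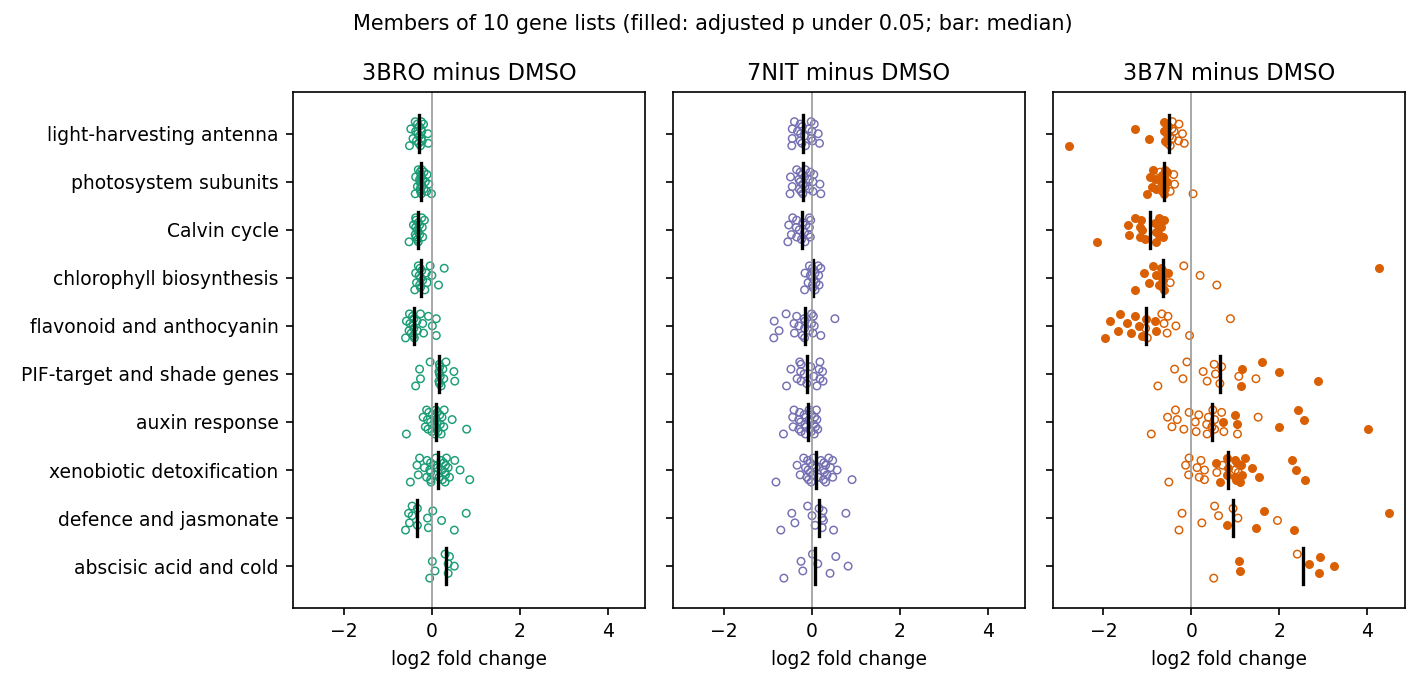
Log2 fold changes against DMSO of the members of 10 gene lists in 3BRO, 7NIT and 3B7N, 1 point per gene, filled where the adjusted p was under 0.05, with a bar at the list median. With 3B7N the members that passed were lower in the antenna, photosystem, Calvin cycle and flavonoid lists. Those that passed in the detoxification and abscisic acid lists were higher. The auxin median with 3B7N turned negative with slide as a block, and GSTU3 after normexp. After quantile normalisation LHCB1.1, LHCB1.3 and PSAK turned positive with 3B7N, and the 7NIT antenna and photosystem tests turned upward.

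In all, 3692 of 23536 genes changed between 3B7N and DMSO by limma (15.7%), 1291 higher and 2401 lower, and 1590 of these changed by a fold of 2 or more, 566 higher and 1024 lower. No slide held both groups. With slide as a block 771 genes changed, 418 of them among the 3692 and all 418 in the same direction, and without DMSO replicate 1 the count was 2133. The authors' deposited table lists 1779 probes for this comparison, with 1322 loci among them, and 1732 of these probes were also called here at a fold of 2 or more, out of 2340 such probe calls. Absolute log2 folds of the authors' deposited table correlated with those here with r of 0.99995 across probes, which are not independent replicates. By direction here, 460 of its probes were higher and 1319 lower. The largest folds in the authors' deposited table were 34.1 for CYP706A6, 24.2 for a probe without a gene name in the files, 23.2 for AT3G10185, 19.3 for PORA and 18.8 for FSD1.

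The comparison of 3BRO with DMSO asks whether the analog that carries only the bromo group changes expression. Without an arm on unsubstituted indazole, a change cannot be assigned to the bromo group itself. FRK1, a receptor-like kinase induced by bacterial flagellin, rose by 1.59 log2 units (SE 0.14, n = 3 arrays per treatment, limma adjusted p = 0.0059), a fold of 3, and was the 1 gene of 23536 that passed, with 886 genes at an unadjusted p under 0.05. FRK1 was at 1.86 with slide as a block (adjusted p = 0.0097), and did not pass without DMSO replicate 3 (1.53) or after normexp background correction (0.20). Slide 1 alone, with a single 3BRO array against 3 DMSO arrays, gave FRK1 at 1.86 and 0 calls by limma, with 1602 genes at an unadjusted p under 0.05. A slide block gave 43 genes. Among the photoreceptor, light signalling and marker genes followed here, CHS was at -0.47 (95% confidence interval -0.96 to 0.02), LHCB1.1 at -0.29 (-0.65 to 0.07), CRY1 at -0.11 (-0.43 to 0.21), CRY2 at -0.18 (-0.48 to 0.13), PHYA at 0.15 (-0.31 to 0.61), HY5 at 0.20 (-0.30 to 0.70) and PIF4 at 0.34 (-0.81 to 1.48). PHOT1, PHYB and COP1 were at 0.12, 0.01 and 0.16, and none of these 10 genes passed.

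No member of any of the 29 lists passed with 3BRO (0 of each, over all genes and adjusted over the list alone), but camera with its preset correlation placed 7 lists lower. These were the antenna (median -0.29, camera adjusted p = 3.7e-07), photosystems (-0.24, 1.1e-06), Calvin cycle (-0.32, 2.1e-11), chlorophyll (-0.24, 0.00051), flavonoid (-0.41, 0.00026), plastid-encoded (-0.35, 2.1e-11) and mitochondrion-encoded genes (-0.63, 5e-20). The xenobiotic list was higher (0.13, adjusted p = 0.04), and with slide as a block its median was 0 (adjusted p = 0.72), the test turning downward. Its call was lost on leaving out DMSO 1, DMSO 2, 3BRO 2 or 3BRO 3 (adjusted p up to 0.39). None of these 8 was called with an estimated correlation, at adjusted p = 0.72 with an estimated correlation for the 7 lower lists and 0.73 for the xenobiotic list. After quantile normalisation the antenna (adjusted p = 0.15) and photosystem (adjusted p = 0.29) calls ended. With slide as a block the mitochondrion-encoded genes were at -0.91 (adjusted p = 2.1e-13), the Calvin cycle at -0.24 (adjusted p = 0.0042) and the flavonoid genes at -0.25 (adjusted p = 0.43). Only with that block were 6 further lists lower and heat shock genes higher (0.48, adjusted p = 0.014). The lower ones were the auxin (-0.57, adjusted p = 0.00016) and PIF-target lists (-0.53, adjusted p = 0.049), both turned from an upward test, and the cell wall, root, cytochrome P450 and SAUR lists. With the block no list was called with an estimated correlation (adjusted p of 0.60 or above). Examples were SBPASE of the Calvin cycle at -0.36, C4H of phenylpropanoid synthesis at -0.43, ATMG01040 at -0.73, and GSTF6 and GSTF7, both glutathione transferases, at 0.52 and 0.64, none of which passed.

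The comparison of 7NIT with DMSO asks the same of the analog that carries only the nitro group, with the same limit. FSD1 fell by 2.26 log2 units (SE 0.20, n = 3 arrays per treatment, limma adjusted p = 0.005), while CCS, the copper chaperone that loads copper superoxide dismutases, rose by 1.05 (SE 0.11, adjusted p = 0.016). FRO5, a metal reductase related to FRO4, fell by 3.23 (SE 0.35, adjusted p = 0.016), at least 1.97-fold, but stood at 0.21 after normexp background correction. AT1G77746 rose by 3.16 (SE 0.37, adjusted p = 0.021), at least 2.07-fold, and AT1G67635 by 1.29 (SE 0.15, adjusted p = 0.021). SWEET8, of the sugar transporter family, rose by 1.85 (SE 0.24, adjusted p = 0.045), at least 2.27-fold, whereas another probe of SWEET8 was at -0.26 (adjusted p = 0.85). These 6 genes were the ones that passed, with 1860 at an unadjusted p under 0.05, and no slide held both groups. The values with slide as a block were -1.23 for FSD1, 1.37 for CCS, -3.66 for FRO5, 2.88 for AT1G77746, 1.02 for AT1G67635 and 1.27 for SWEET8, at adjusted p of 0.15, 0.066, 0.06, 0.19, 0.21 and 0.35, and 34 other genes changed instead. FSD1 and CCS kept their call after normexp background correction and FSD1 and FRO5 in a fit of the 2 groups alone, and the other 4 lost it in each case. No gene passed without DMSO replicate 1 or without any single 7NIT array (0 genes each by limma, with 1214 to 2249 at an unadjusted p under 0.05). With other omissions 1 passed without DMSO replicate 2 and 1 without DMSO replicate 3, and 12 passed without 3BRO replicate 1.

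Of the followed genes, CHS was at -0.15 with 7NIT (95% confidence interval -0.65 to 0.34), LHCB1.1 at -0.44 (-0.80 to -0.09, adjusted p = 0.58), CRY1 at -0.10 (-0.42 to 0.21), CRY2 at -0.20 (-0.50 to 0.11), PHYA at -0.10 (-0.56 to 0.36), HY5 at 0.07 (-0.44 to 0.57) and PIF4 at 0.11 (-1.04 to 1.26), and PHOT1, PHYB and COP1 at 0.05, 0.04 and 0.15. None of these 10 passed. Of the members of the 29 lists FSD1 in the oxidative stress list was the 1 that passed over all genes. Adjusted over the list alone, 3 Calvin cycle genes were lower, 1 oxidative stress gene was lower and 2 were higher, and 2 mitochondrion-encoded genes were lower and 1 higher. Camera with its preset correlation placed 10 lists lower: antenna (median -0.19, adjusted p = 0.003), photosystems (-0.20, 0.00087), Calvin cycle (-0.22, 4.1e-06), cell wall (-0.14, 0.042), seed storage (-0.88, 1.1e-06), plastid-encoded (-0.32, 4.4e-11), mitochondrion-encoded (-0.65, 1.6e-15), cytochromes P450 (-0.18, 2.1e-07), extensins and proline-rich wall proteins (-0.14, 0.035) and SAUR (-0.11, 0.0039). None of the 10 was called with an estimated correlation, at adjusted p from 0.58 to 0.74 with an estimated correlation. The antenna and photosystem tests turned upward, uncalled, after quantile normalisation (adjusted p = 0.45 and 0.95), where the Calvin cycle (adjusted p = 0.43) and extensin (adjusted p = 0.062) calls ended too. The extensin (adjusted p = 0.23) and SAUR (adjusted p = 0.16) calls ended after normexp background correction. Under a slide block the mitochondrion-encoded genes were at -1.20 (adjusted p = 1.3e-06), the SAUR family at -1.07 (adjusted p = 4.3e-06) and the cytochromes P450 at -0.52 (adjusted p = 1.3e-06), while the Calvin cycle stood at 0.11 (adjusted p = 0.39) and the plastid-encoded genes at 0.08 (adjusted p = 0.99). The first 3 were lost at adjusted p of 0.81, 0.61 and 0.29 with an estimated correlation. Lists called only with that block were auxin (-1.60, adjusted p = 1.6e-07), PIF targets (-0.98, adjusted p = 0.0087), peroxidases (-0.90, adjusted p = 0.0053) and WRKY factors (-0.25, adjusted p = 0.038), lower, and heat shock, turned to higher (adjusted p = 0.0087). They were not called at adjusted p from 0.29 to 0.81 with an estimated correlation. The antenna (-0.28, adjusted p = 0.19), photosystem (-0.10, adjusted p = 0.77) and seed storage (0, adjusted p = 0.93, the test turning upward) calls were lost with that block as well. Leaving out DMSO 3 ended the antenna, photosystem, cell wall, extensin and SAUR calls (adjusted p up to 0.47). The cell wall call was also lost without 7NIT 1 or 7NIT 3, the extensin call without DMSO 2 or 7NIT 1 and the SAUR call without 7NIT 2 (adjusted p up to 0.42).

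For 7NIT the authors' deposited table lists 14 probes, with 5 loci among them, and 3 of the 14 were called here out of 11 such probe calls. All 14 were lower here. The authors' deposited table gives folds of 18.6 for the unnamed probe that was also prominent with 3B7N, 6.02 for ZIP2, a metal transporter, 5.61 and 5.58 for 2 probes without a gene name, and 5.05 for AT2G07716. FSD1, at 3.52, was among its 5 smallest folds. That fold belongs to another probe than the one that represents FSD1 here, and the other probe was at -1.82 log2 units here (limma adjusted p = 0.00082). ZIP2 and AT2G07716 did not pass here, at -2.59 (adjusted p = 0.11) and -2.34 (adjusted p = 0.12). No probes of the authors' deposited table concern 3BRO.

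Against 3BRO at the same dose, which lacks the nitro group, 3B7N differed in 1768 genes by limma, 641 higher and 1127 lower. NATA1 was higher with 3B7N by 6.50 log2 units (SE 0.55, n = 3 arrays per treatment, adjusted p = 0.00024), at least 25.3-fold, DIN11 by 5.51 (SE 0.33, adjusted p = 3.4e-05), ENODL1 by 5.46 (SE 0.35, adjusted p = 5.6e-05), CYP71A13 by 4.27 (adjusted p = 0.0013), at least 8.59-fold, and PORA by 4.12 (adjusted p = 0.00034). PIN5 was lower at -4.77 (SE 0.70, adjusted p = 0.0042), CYP706A6 at -4.50, FRO4 at -4.16, AT4G34550 at -4.14 and the microRNA gene MIR408 at -4.12, at least 4.8-fold. These 10 genes passed with slide as a block as well, at adjusted p of 0.016 or below. Normexp background correction ended the calls of NATA1 (2.09, adjusted p = 0.17), ENODL1 (2.54, adjusted p = 0.064), CYP71A13 (0.67), PIN5 (-1.72), FRO4 (-1.66) and MIR408 (-1.01). PIN5 (adjusted p = 0.057) and FRO4 (adjusted p = 0.064) did not pass in a fit of the 2 groups alone, and on slide 2 alone DIN11 was the 1 of the 10 that passed. CHS was lower with 3B7N than with 3BRO at -1.37 (SE 0.22, adjusted p = 0.0063), HY5 at -0.94 (SE 0.23, adjusted p = 0.032), and PHYA higher at 0.86 (SE 0.21, adjusted p = 0.032), while LHCB1.1 did not differ by the test (-0.27, 95% confidence interval -0.63 to 0.09). Calvin cycle genes were lower with 3B7N, 11 of 18 over all genes and 18 adjusted over the list alone (median -0.67, camera adjusted p = 1.1e-12, adjusted p = 0.23 with an estimated correlation). In the xenobiotic list 12 of 31 were higher, or 19 adjusted over the list alone (median 0.75, camera adjusted p = 1.1e-11, adjusted p = 0.078 with an estimated correlation). Of the defence and jasmonate genes 5 of 13 were higher, or 7 adjusted over the list alone (median 1.45, camera adjusted p = 6.3e-07, adjusted p = 0.034 with an estimated correlation, or 0.13 with slide as a block as well). Blocking on slide gave 1172 genes, 759 of them among the 1768, and slide 2 alone, with 2 arrays of each, called 1 gene. The count was 853 without 3BRO replicate 2, whose file holds rounded signals, and 1037 without 3BRO replicate 3.

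Against 7NIT, which lacks the bromo group, 3B7N differed in 4371 genes by limma, 1427 higher and 2944 lower. NATA1 was higher with 3B7N by 6.34 log2 units (SE 0.55, n = 3 arrays per treatment, adjusted p = 0.00017), at least 26.9-fold, ENODL1 by 5.98 (SE 0.35, adjusted p = 3.1e-05), DIN11 by 5.57, CYP71A13 by 5.19, at least 9.4-fold, and AT3G29060 by 4.61, at least 10.3-fold. AT2G30766 was lower at -5.10 (SE 0.92, adjusted p = 0.0043), CYP706A6 at -4.72, AT4G34550 at -4.63, AT3G10185 at -4.37 and PIN5 at -4.31. These 10 genes passed with slide as a block, at adjusted p of 0.028 or below. Normexp background correction ended the calls of NATA1 (1.32, adjusted p = 0.22), ENODL1 (1.82, adjusted p = 0.095), CYP71A13 (0.03) and AT3G29060 (0.09), and on slide 3 alone PIN5 did not pass (-2.46, adjusted p = 0.064). CHS was lower at -1.68 (SE 0.22, adjusted p = 0.0011), HY5 at -0.81 (SE 0.23, adjusted p = 0.033) and FSD1 at -1.98 (SE 0.20, adjusted p = 0.00029), and PHYA was higher at 1.11 (SE 0.21, adjusted p = 0.0053). LHCB1.1 did not differ by the test (-0.12, 95% confidence interval -0.48 to 0.24), and FRO5 was not well above background on any array of either compound. In chlorophyll biosynthesis 13 of 18 genes were lower and PORA higher, or 14 and 1 adjusted over the list alone (median -0.67, camera adjusted p = 0.00033, adjusted p = 0.40 with an estimated correlation). Of the xenobiotic genes 15 of 31 were higher, or 17 adjusted over the list alone (median 0.62, camera adjusted p = 3.6e-08, adjusted p = 0.15 with an estimated correlation). Of the auxin response genes 8 of 28 were higher, or 12 adjusted over the list alone (median 0.50, camera adjusted p = 1.1e-05, adjusted p = 0.40 with an estimated correlation). The auxin median with slide as a block was 0.83 (adjusted p = 1.3e-08), with adjusted p = 0.24 with an estimated correlation. Blocking on slide gave 1952 genes, 1693 of them among the 4371, and slide 3 alone called 1556 with a single 3B7N array, which was assumed to vary like the others. The count was 2092 without 7NIT replicate 1 and 2226 without 7NIT replicate 3.

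The analogs that carry a single substituent differed from each other in 5 genes by limma, with 2201 genes at an unadjusted p under 0.05. With 7NIT, CCS was higher than with 3BRO by 1.06 log2 units (SE 0.11, n = 3 arrays per treatment, adjusted p = 0.015) and so was AT1G67635 (95% confidence interval 0.96 to 1.63, adjusted p = 0.024). FSD1 was lower at -2.02 (SE 0.20, adjusted p = 0.0076). FRK1 was lower at -2.02 (SE 0.14, adjusted p = 0.00051) and MIR408 at -3.60 (SE 0.45, adjusted p = 0.032), at least 3.78-fold, but after normexp background correction FRK1 stood at 0.10 and MIR408 at 0.23. None of the 5 passed with slide as a block (adjusted p from 0.12 to 0.19) and limma called 0 genes, with 3178 at an unadjusted p under 0.05. The count was 1 without 7NIT replicate 1 or 3, 2 without DMSO replicate 1, 3 without 3BRO replicate 3 or 3B7N replicate 2, and 16 without 3B7N replicate 3. CHS (0.31, 95% confidence interval -0.18 to 0.80), PHYA (-0.25, -0.71 to 0.21), DIN11 (-0.06, -0.78 to 0.66) and PORA (-0.07, -0.88 to 0.75) did not differ by the test, and NATA1 was not well above background on any array of either. Over all genes, the interval of the difference between 7NIT and 3BRO lay within a fold of 2 for 78.5% of genes, against 62.8% for 3B7N and 7NIT and 70.8% for 3B7N and 3BRO, with a median interval half-width of 0.45 log2 units.

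The interaction tested whether the change with 3B7N equals the sum of the changes with 3BRO and 7NIT, each against DMSO. No group received indazole without a substituent. An effect of the shared indazole ring therefore cannot be told apart from an interaction of the bromo and nitro groups. For DIN11 the change with 3B7N exceeded the sum by 5.15 log2 units (SE 0.46, n = 3 arrays per treatment, limma adjusted p = 0.0024). NATA1, ENODL1, CYP71A13 and AT3G29060 passed above the sum too, but were not well above background on any DMSO array, so the size above the sum is not known for them. Below the sum were CYP706A6 at -4.13 (SE 0.58, adjusted p = 0.016), AT4G34550 at -4.04, AT1G29720 at -3.40 and AT1G07450 at -3.03, as was AT1G77746, which was not well above background with DMSO or 3BRO. Of these 10 genes DIN11, ENODL1 and AT1G29720 passed with slide as a block (adjusted p = 0.031 each). The other 7 did not, such as CYP706A6 (adjusted p = 0.066) and AT4G34550 (adjusted p = 0.17). In all 155 genes passed, 82 above and 73 below the sum. The count was 96 with slide as a block, of which 35 were among the 155, and 721 with array weights. After normexp background correction every call ended (0 genes by limma, with 2584 at an unadjusted p under 0.05), and DIN11 was at 2.99 and CYP706A6 at -2.75. The count lay between 31 without 3BRO replicate 2, the array with rounded signals, and 400 without 3B7N replicate 2, and moved by more than 1.5-fold on leaving out any array other than 3B7N replicate 1 or 3.

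Log2 fold changes against DMSO were compared across genes, which are not independent replicates. Those of 3B7N and 3BRO correlated with r of 0.53, where simulated unchanged groups against a shared simulated DMSO group gave 0.45 on average (95% of simulations from -0.21 to 0.90), with a covariance of 0.11 against 0.043. Those of 3B7N and 7NIT correlated with r of 0.28, against 0.50 (-0.14 to 0.93), with a covariance of 0.063 against 0.049, and r was 0.0051 after normexp background correction. Those of 3BRO and 7NIT correlated with r of 0.46, against 0.51 (-0.18 to 0.89), with a covariance of 0.05 against 0.053. FSD1 and FRO5 fell with both 3B7N and 7NIT, and 3 genes rose with both, where independent lists would share 0.20 and 0.22 genes and the simulations shared 0.01 and 0.02. AT1G67635 passed with both in opposite directions, at 1.29 with 7NIT (limma adjusted p = 0.021) and -1.11 with 3B7N (limma adjusted p = 0.0012). The simulations hold no changed genes, so their shared counts were low by design and decide nothing here. Part of any excess may come from the shared DMSO arrays. Of comparisons that share no arrays, 3B7N against 7NIT correlated with 3BRO against DMSO with r of 0.28, against -0.082 in simulations (95% from -0.72 to 0.62), and 3B7N against 3BRO with 7NIT against DMSO with r of 0.07, against -0.025 (-0.80 to 0.72).

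**Figure D4:**
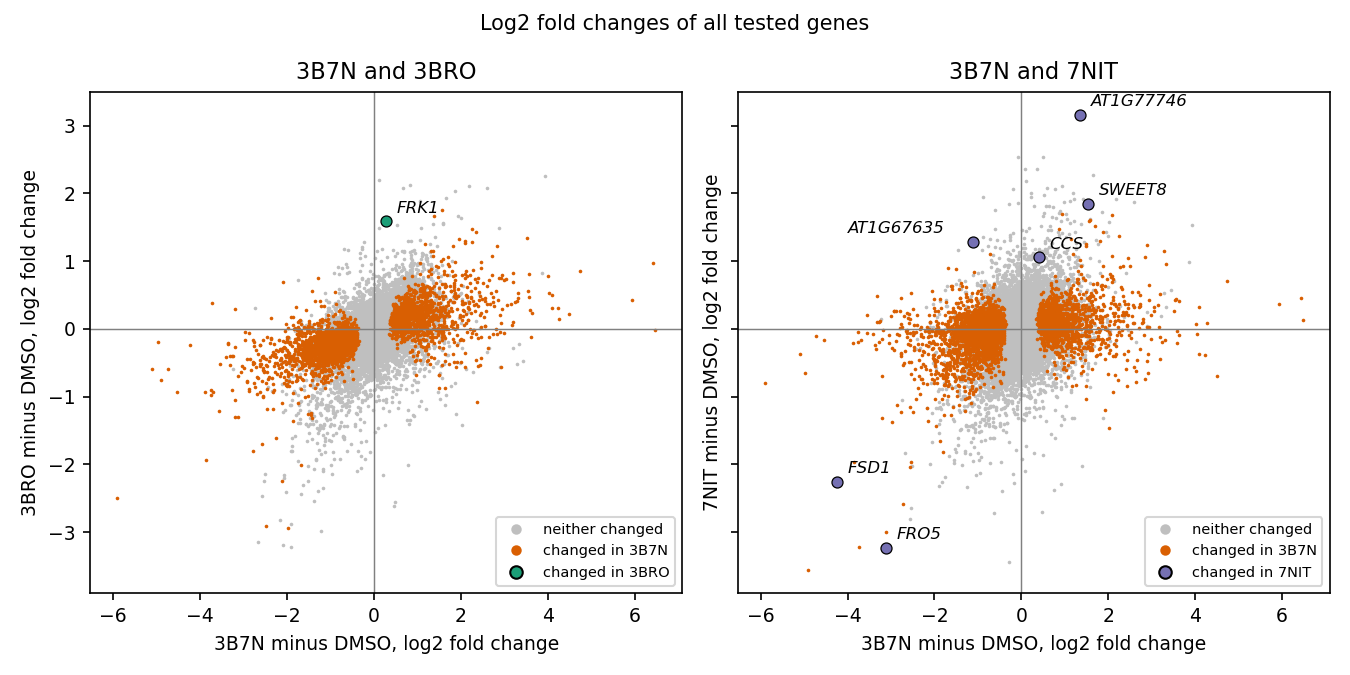
Log2 fold change against DMSO of each tested gene with 3B7N on the horizontal axis and with 3BRO (left) or 7NIT (right) on the vertical axis, with genes that changed against DMSO coloured. Of the genes named on the plot, FRK1 changed with 3BRO, and FSD1, FRO5, CCS, SWEET8, AT1G67635 and AT1G77746 with 7NIT, where FRO5 turned after normexp background correction.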

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

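The tests of slides, scan days and 3B7N replicate 1 were chosen only after the results were seen, while the splits of the arrays were planned. The interaction stood out because the change with 3B7N differed from the sum of the changes with 3BRO and 7NIT, in 155 genes. Without an arm on unsubstituted indazole, the interaction cannot be assigned to the bromo and nitro groups alone. Its genes named by the rule had fitted values of NATA1 at 6.37, DIN11 at 5.15, ENODL1 at 5.01, CYP71A13 at 4.96 and AT3G29060 at 4.31 above the sum, and CYP706A6 at -4.13, AT4G34550 at -4.04, AT1G29720 at -3.40, AT1G07450 at -3.03 and AT1G77746 at -2.95 below it. The values of NATA1, ENODL1, CYP71A13, AT3G29060 and AT1G77746 rest on background readings with DMSO, so their true sizes and order are not known. Of 100 regroupings of the 12 arrays, 2 gave as many genes, the real one among them, but regroupings that part the 3B7N arrays put their shift into the residual and can call few genes. The 1 other that kept the 3 arrays of 3B7N together gave 2550 genes. It labelled the 3B7N arrays as DMSO and the DMSO arrays as 7NIT, so its contrast contains the difference of 3B7N from DMSO. The next highest gave 8, so these regroupings decide nothing about the interaction.

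Probes without a locus in the files were outside the main tests and showed a signal as well. Of 3628 such probes 411 changed between 3B7N and DMSO, 93 higher and 318 lower, 6 changed with 7NIT, 4 higher and 2 lower, and 0 with 3BRO by the same limma fit.

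The number of genes that changed with 3B7N, 3692, was weighed against differences between slides or scan days. 7NIT shares no slide and no scan day with DMSO either, and changed 6 genes, which argues against scan day or slide 3 alone as the account of the count. The 7NIT arrays all lay on slide 3, so their count says nothing of slide 2, which held 3B7N replicates 1 and 2. Without 3B7N replicate 1, which lay furthest out, 2767 genes changed, so that array alone does not account for it. With slide as a block 771 genes changed, where the block also called 36% rather than 86% of simulated changes of 2 log2, so a slide or day effect on single genes whose call ended is neither shown nor excluded. The simulation changed a far smaller share of genes than was called in the data, so its figures may not carry over. An effect of the compound on these transcripts remains a hypothesis, found and tested on the same arrays.

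The 3 against 3 designs allow 10 splits, too few for a share under 0.05. Every other split also mixes the groups compared, so a large difference between them enters the residual and few genes can be called. The gene counts of the other splits were therefore bound to be low, and they decide nothing. With 3B7N against DMSO the real split gave 3692 genes and 15 lists and the highest other split 0 genes and 11 lists, with 1 of 10 splits as large in each case. With 3BRO against DMSO the real split gave 1 gene and 8 lists and the highest other 1 gene and 13 lists, with 2 and 8 of 10 splits as large. With 7NIT against DMSO the real split gave 6 genes and 10 lists and the highest other 0 genes and 16 lists, with 1 and 8 of 10 splits as large. Between compounds the real split gave 1768 genes for 3B7N against 3BRO (highest other 8), 4371 for 3B7N against 7NIT (highest other 0) and 5 for 7NIT against 3BRO (highest other 0), each with 1 of 10 splits as large.

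The auxin response genes, higher with 3B7N than with DMSO, were weighed against the same differences between slides. Among the 7 pairs of arrays on the same slide, 3B7N minus another compound gave a lowest list median of -0.09, with -0.09 to 0.21 against 3BRO on slide 2 and 0.60 to 1.00 against 7NIT on slide 3. On slide 1 the pairs of 3BRO minus DMSO lay between -0.71 and -0.24. For the PIF-target and shade genes, the same pairs of 3B7N minus another compound gave list medians of 0.2 to 0.52 against 3BRO and 0.44 to 0.93 against 7NIT. No slide holds 3B7N and DMSO together, so a change with the compound and a difference between slides cannot be told apart for either list.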

How the results depend on the processing

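The fits to single slides, slide as a random block, and the slide and scan-day blocks of the lists were tests chosen only after the results were seen. All genes called both with and without an alternative kept their direction. The cause of the shifts below was not tested except where fewer arrays or a stricter threshold make it plain. After normexp the median of all genes was -0.147 log2 for 3B7N against DMSO (from -0.017), 0.12 for 7NIT against DMSO (from 0.029), -0.242 for 3B7N against 7NIT (from -0.033), 0.169 for 7NIT against 3BRO (from 0.043) and -0.2 for the interaction (from -0.042). Between 77.1% and 84.6% of probes were well above background per array, which limits what can be said of the dimmer ones.

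For 3B7N against DMSO, 3692 genes became 1724 after normexp, 771 with a slide block, 611 with a scan-day block, 1901 with the 2 groups alone and 1590 at a fold of 2 or more. Quantile normalisation gave 1790 higher and 1914 lower, 51.7% lower against 65%. For 3BRO against DMSO, 1 gene became 0 after normexp, with trend and robust, with the 2 groups alone and on slide 1 only (283, 868, 924 and 1602 at an unadjusted p under 0.05 by limma), 43 with a slide block, 32 with a scan-day block and 3 with array weights. For 7NIT against DMSO, 6 became 12 after quantile normalisation, 2 after normexp, 3 among probes well above background on all arrays, 34 with a slide block, 96 with a scan-day block and 70 with array weights. For 3B7N against 3BRO, 1768 became 650 after normexp, 1172 with a slide block, 231 with the 2 groups alone, 825 at a fold of 2 or more and 1 on slide 2 only. For 3B7N against 7NIT, 4371 became 2374 after normexp, 1952 with a slide block, 1691 at a fold of 2 or more and 1556 on slide 3 only. For 7NIT against 3BRO, 5 became 8 after quantile normalisation, 1 after normexp, 0 with a slide block (3178 at an unadjusted p under 0.05 by limma), 12 with a scan-day block and 90 with array weights. For the interaction, 155 became 0 after normexp (2584 at an unadjusted p under 0.05 by limma), 92 without a filter, 96 with a slide block and 721 with array weights. Of the 33 list calls, 0 were left with an estimated correlation and 11 by fry. Of the list calls quantile normalisation ended 3 for 3B7N, 2 for 3BRO and 4 for 7NIT, and normexp 2, 0 and 2.

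Leaving out 1 array gave 2133 (DMSO 1) to 3840 (3BRO 1) genes for 3B7N against DMSO, 0 (DMSO 3) to 2 (DMSO 2 or 3B7N 3) for 3BRO, 0 (DMSO 1 or any 7NIT array) to 12 (3BRO 1) for 7NIT, 853 (3BRO 2) to 1762 (DMSO 3) for 3B7N against 3BRO, 2092 (7NIT 1) to 4587 (3BRO 1) for 3B7N against 7NIT, 1 (7NIT 1 or 3) to 16 (3B7N 3) for 7NIT against 3BRO, and 31 (3BRO 2) to 400 (3B7N 2) for the interaction. With a replicate block the counts were 4312, 1, 13, 1962, 5025, 5 and 163 in the order above. Of 18 same-number pairs 11 correlated above 0.1 (from -0.1593 to 0.4438), and 9 of 12 arrays correlated best with their own number, a hint from the data and not from the design.

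Reversed values after normexp were 0.21 for FRO5 (7NIT against DMSO), 0.23 for MIR408 and 0.1 for FRK1 (7NIT against 3BRO), and -0.22 for GSTU3 and -0.2 for PRX52 (3B7N against DMSO). After quantile normalisation, with 3B7N, they were 0.08 for LHCB1.3, 0.04 for LHCB1.1, 0.01 for PSAK, 0.02 for PYK10 and 0.01 for ATCG01240. With a slide block IAA17 was at -0.12. List tests that turned, with slide and scan-day blocks in that order, had adjusted p of 0.27 and 0.56 (auxin) and 0.018 and 0.023 (SAUR) for 3B7N, and 0.00016 and 0.00026 (auxin) and 0.72 and 0.7 (xenobiotic) for 3BRO. With the slide block they were 0.049 for PIF targets with 3BRO, and 0.39 (Calvin cycle), 0.93 (seed storage) and 0.0087 (heat shock) for 7NIT. Of these, the tests called with the slide block were lost at adjusted p of 0.74 (SAUR), 0.6 (auxin and PIF targets) and 0.52 (heat shock) with an estimated correlation. After quantile normalisation they were 0.45 (antenna) and 0.95 (photosystems) for 7NIT. With 3B7N against DMSO, of 111 named genes that had passed, 30 kept their call with a slide block, 80 lost it and 1 reversed. After normexp 65 kept it, 44 lost it and 2 reversed, and with the 2 groups alone 76 kept it and 35 lost it.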

Other observations

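The copper and iron lists below, and the tests made with them, were chosen only after their genes' values had been seen. The p-values of their set tests therefore describe these lists and cannot serve as support. Genes that Arabidopsis activates when copper is scarce were lower with 3B7N. Of 8 such genes 7 fell, among them the copper-transport genes COPT2 (-1.21) and ZIP2 (-2.72), the copper chaperone CCH (-1.26) and the microRNA gene MIR408, with a list median of -2.92 (camera adjusted p = 7.1e-09, adjusted p = 0.049 with an estimated correlation). With 7NIT all 8 values were negative and 2 passed, FSD1 (-2.26) and FRO5 (at least 1.97-fold lower, or at 0.21 log2 after normexp background correction), with a median of -2.42 (camera adjusted p = 1.2e-18, adjusted p = 0.0034 with an estimated correlation). With 3BRO 0 of 8 passed by limma, and the median was -0.30 (camera adjusted p = 0.0079, adjusted p = 0.64 with an estimated correlation).

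Of the copper superoxide dismutase genes CSD1 and CSD2 and their chaperone CCS, CCS alone passed with 7NIT, but all 3 were positive and the list was higher (median 0.85, camera adjusted p = 9.4e-08, adjusted p = 0.025 with an estimated correlation), also with slide as a block (adjusted p = 0.0044). The list is below the minimum of 5 members set for the planned lists, and was chosen after CCS had passed. Its set test therefore cannot serve as support. With 3B7N 2 of the 3 rose and the list was not called (median 0.40, camera adjusted p = 0.076), and with 3BRO 0 passed by limma. Iron-deficiency genes had medians of -0.70 with 3B7N, where NAS4 fell by 2.02 and OPT3 by 0.80, -0.48 with 7NIT and -0.34 with 3BRO. At camera's preset correlation the list was lower with each (adjusted p = 0.013, 0.0057 and 0.036). These calls were lost at adjusted p of 0.29, 0.35 and 0.64 with an estimated correlation. With slide as a block the list was lower with 3B7N and 7NIT (camera adjusted p = 0.011 and 0.027) but not with 3BRO (0.06).

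The hypothesis was that the nitro compounds may lower the copper-deficiency transcripts, against technical accounts. With 3B7N the pairs with 3BRO on slide 2 had a highest list median of -2.15, so the list was lower within 1 slide. With 7NIT the pairs with 3BRO scanned on the same day had a highest median of -1.85. However, FRO4 and MIR408 were among the lowest named genes of 3B7N against 3BRO, and FSD1 and MIR408 passed in 7NIT against 3BRO. Low pair medians were therefore partly built into the list and cannot decide on slide or scan day. A slide 3 difference with 7NIT stays open as well. The blocked median of -1.39, though still called lower (camera adjusted p = 9.4e-07), rests on 1 array per link between slides. That bound on links was added after the value was known. Background at dim probes could account for part of the size with both compounds, as the 5 of 8 members well above background on all arrays had a median of -1.01 with 7NIT and -1.26 with 3B7N, although that selection leaves out members that fell, and the 4 brighter by mean signal gave -0.78 with 7NIT and -1.23 with 3B7N. For 7NIT the slide 3 and scan-day accounts therefore stay open for the whole shift and background for part of it. For 3B7N slide and scan day were not decided either.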
